A study of Mus musculus with 10 samples.

How the data were processed

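RNA from adult mouse ileum (C57BL/6) was measured on 10 one-colour Agilent mouse arrays, 2 for each of 5 groups, and samples were grouped by the transgenes, the DOX treatment and the replicate numbers of the labels. RNA was labelled with Cy3 after linear amplification, per the labels. The deposited scanner files hold intensity values per spot that Agilent Feature Extraction had background-subtracted and detrended, with surrogates for spots not above background and no normalization between arrays, per the file headers. The headers give Feature Extraction 9.5.3.1 for slide 1, 10.7.1.1 for slide 2 and 10.7.3.1 for slide 3, and the labels name 9.1 for all. The files also hold the mean intensity of each spot (for slide 3 the median) and the median intensity of its local background, without further treatment per the file headers, and flags for spots. A deposited table of normalized values covers the 4 TetON-Sox2 arrays only. In it, 72.2 to 75.3% of probes had the same ratio to the processed intensity of the scanner file and the other 24.7 to 27.8% stood at a floor, and no step behind it is given in the sources used here.

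Each array held 45018 spots, of which 1639 were controls. Spots flagged as outliers (45 to 65 per array) were left out and spots of a probe averaged. Of 41174 non-control probes, 31 with no unflagged spot on some array were dropped and 41143 used. The log2 of the processed signal was taken and the array's 75th percentile subtracted. That percentile was a signal of 544.1 to 1614.5, no probe was saturated, and 63.5 to 70.5% of probes were well above background, the lowest of them at signals of 9.51 to 12.32. Probes well above background on both arrays of at least 1 group were kept (28760). Probes were named through RefSeq tables (80.3%) or kept the name in the file (8123), which gave 27550 gene names, and the probe with the highest mean stood for each gene, so that 19052 genes were tested. Coordinates are those of the files, on build NCBI36/mm8. Where a gene was not well above background in 1 of the groups compared, its fold is given as at least that against the lowest signal well above background.

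Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 arrays (5 residual degrees of freedom, 3.3 prior degrees of freedom) and empirical Bayes errors, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Of the comparisons, 7 were planned, including the interaction of the transgenes. Gene lists (35, fixed with the comparisons and alternatives before the data were examined) were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists of the comparison. Members were counted as called over all genes and as called when adjusted over the list alone. Some lists share measured members. Those of intestinal stem cells and Wnt targets share 9. Those of stomach and foregut and of squamous epithelium share 1, Trp63. Named genes were Sox2, Pou5f1, Sox21, Cdx2 and Nanog in every comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap between groups, and from each list up to 4 members with the smallest p, and fewer were named than this allows. Comparisons with shared controls were set beside 100 simulations of unchanged groups. These drew every gene and array independently, so effects shared across genes or arrays were not simulated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

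Alternatives were normexp background correction (offset 50) of the spot means with quantile normalization, quantile normalization alone, no filter on dim probes, all probes and a variance trend. Others were a fit to only the groups compared, the replicate number or the slide as a block, and the authors' normalized table for the TetON-Sox2 arrays. Each array was also left out in turn, where the lone array of a group is assumed to vary like the other groups. The slide block was fitted only for comparisons within slides and their difference. There it can change nothing, since each group lay on 1 slide, and comparisons between slides cannot be estimated with it. A floor at the lowest signal well above background, a fit without the Oct4 group, the difference of the within-slide responses and a pair of responses without shared arrays (Sox2 +DOX against Sox2 -DOX with Oct4 +DOX against rtTA +DOX) were added after the files were seen. The scripts were tested on simulated data. With 200 of 19052 genes changed between Sox2 +DOX and Sox2 -DOX in 20 runs, 1.04% of genes changed by a log2 of 1, 39% of those changed by 2 and 84% of those changed by 3 were called, and 5.6% of calls were false. The median standard error of a log2 change was 0.39. Replicates correlated with r of 0.96 to 0.98 within groups, and the root mean square difference of replicates ran from 0.62 in Sox2 -DOX to 0.98 in Sox2xOct4 +DOX.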

Results

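Gene expression in the ileum, the last part of the small intestine, was measured in adult mice on 10 one-colour arrays that fall into 5 groups of 2. TetON mice carry a transgene that is transcribed when doxycycline (DOX) activates the regulator rtTA. The groups were TetON-Sox2 mice without DOX (Sox2 -DOX), TetON-Sox2 mice given DOX (Sox2 +DOX), mice with rtTA and no Sox2 transgene given DOX (rtTA +DOX), TetON-Oct4 mice given DOX (Oct4 +DOX) and mice with both transgenes given DOX (Sox2xOct4 +DOX). DOX was given at 2 mg/ml for 2 days, with 1% sucrose, to mice 6 to 8 weeks old. The labels record no sucrose for Sox2 -DOX, so comparisons with that group hold DOX and sucrose together. Sox2 and Oct4 (gene symbol Pou5f1) are transcription factors of early embryonic cells, and Sox2 is also found in foregut epithelium. The series asks what forced expression of Sox2 does to the adult intestine. The number of arrays, 2 per group, limits the precision of every value. The labels number the replicates and speak of animals, but they do not say that the 2 arrays of a group came from separate animals, so p-values measure only the spread between these samples. This spread may be technical except in Oct4 +DOX, whose 2 arrays differed in sex-linked genes, and in Sox2 +DOX, whose 2 arrays differed by at least 13.59 on the log2 scale in the defensin gene Defcr-rs10, chosen after its values were seen. All 4 TetON-Sox2 arrays lay on slide 1, the rtTA and Sox2xOct4 arrays on slide 2 and the Oct4 arrays on slide 3. A comparison between slides therefore holds batch and group together, and they cannot be told apart there.

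The induced genes were examined first. Pou5f1 was read by 1 probe (NCBI36/mm8, chromosome 17, 35118388 to 35118448). Its log2 signal over the array's 75th percentile was 5.49 ± 0.99 in Oct4 +DOX (SD, n = 2) and 1.78 ± 1.22 in Sox2xOct4 +DOX, and it was not well above background on the other 6 arrays. Against rtTA +DOX it was at least 4800-fold higher in Oct4 +DOX (limma adjusted p = 7.4e-05) and at least 366-fold higher in Sox2xOct4 +DOX (adjusted p = 2.4e-04). The Sox2 probe (chromosome 3, 34843400 to 34843459) was not well above background on any of the 10 arrays, with means of -8.23 ± 0.07 in Sox2 +DOX and -7.92 ± 0.12 in Sox2 -DOX. Whether the transgene holds the sequence of that probe is not given in the sources used here, so the probe does not check the Sox2 labels. The probe of Nanog, a pluripotency factor, was also not well above background on any array.

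Sox21, a relative of Sox2, was 71.4-fold higher in Sox2 +DOX than in Sox2 -DOX (log2 change 6.16 ± 0.66, SE, n = 2 against 2, adjusted p = 0.0026) and 31-fold higher in Sox2xOct4 +DOX than in rtTA +DOX (4.95 ± 0.66, adjusted p = 0.0077). The second of these was no longer called without rtTA +DOX replicate 2, at 4.28. Sox21 had 3 probes, which all gave a higher value in both comparisons, and 2 of them were called. Cdx2, a master regulator of intestinal identity, gave log2 changes of -0.98 ± 0.49 (adjusted p = 0.24) in Sox2 +DOX against Sox2 -DOX, -0.08 ± 0.49 (adjusted p = 0.97) in Oct4 +DOX and -1.16 ± 0.49 (adjusted p = 0.2) in Sox2xOct4 +DOX against rtTA +DOX, none of which passed the test.

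**Figure D1:**
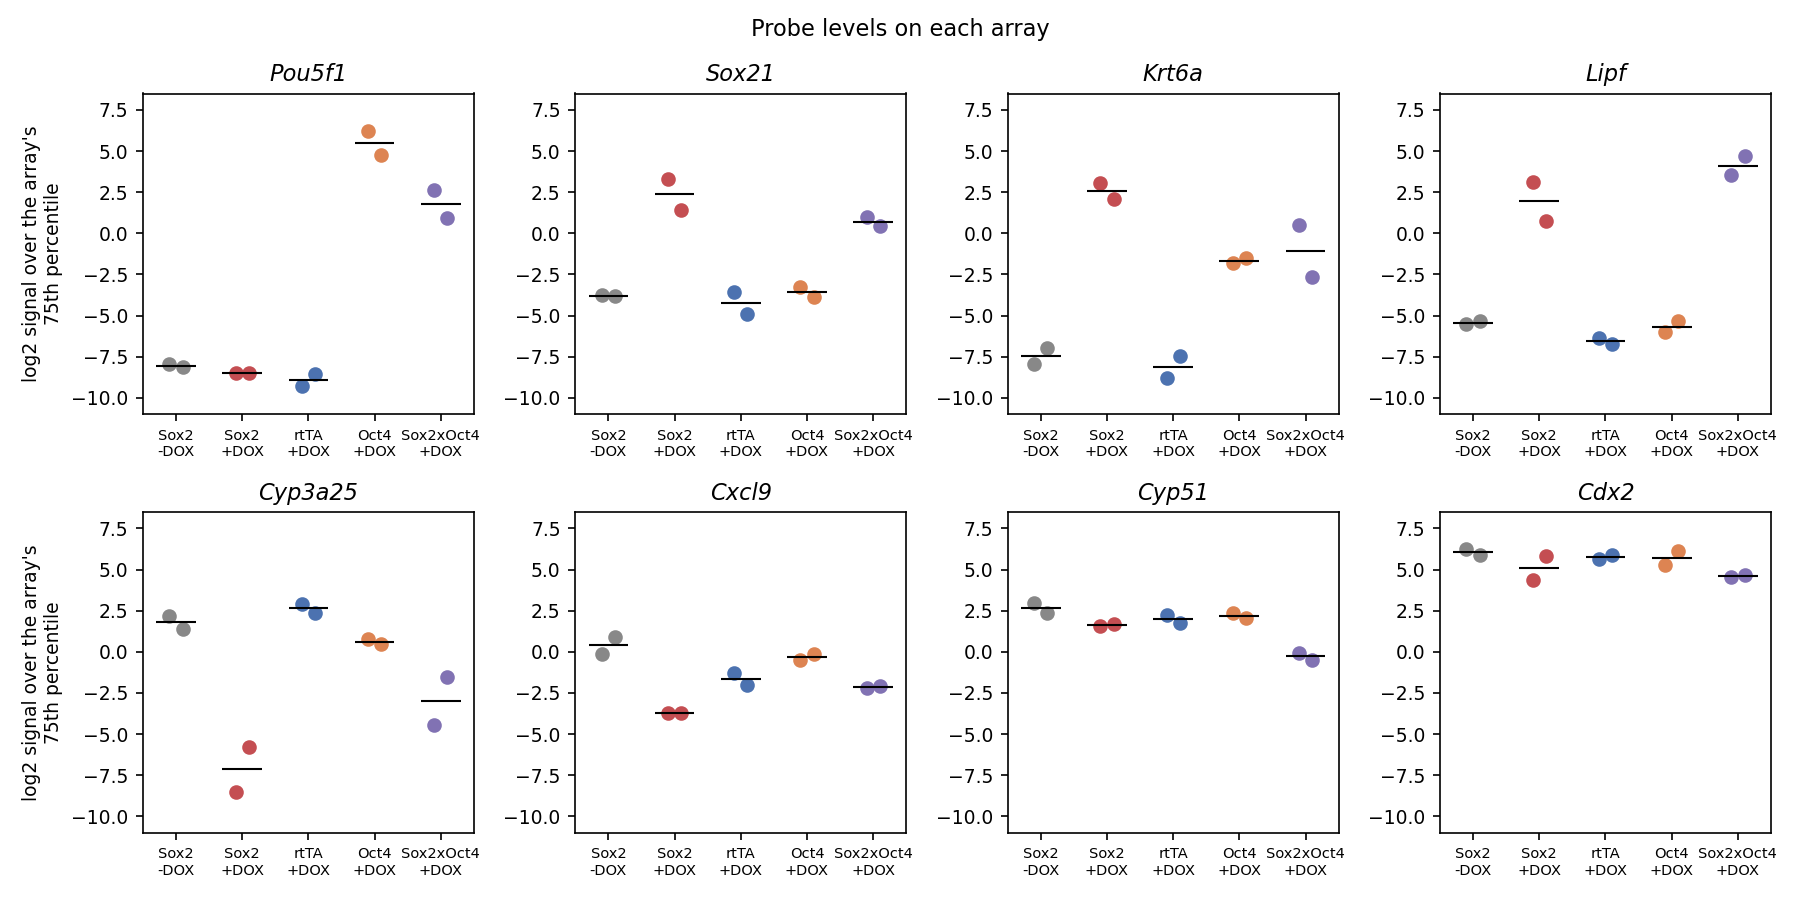
Log2 signal of 8 genes over each array's 75th percentile (y axis) on the 2 arrays of each of the 5 groups (x axis). Points are arrays and bars are group means. Pou5f1 stands at 5.49 in Oct4 +DOX and 1.78 in Sox2xOct4 +DOX, and Cyp51 is lowest in Sox2xOct4 +DOX.

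Sex-linked genes also differed between arrays. Eif2s3y, a Y-linked gene, was well above background on all 4 TetON-Sox2 arrays (1.61 to 2.10) and on Oct4 +DOX replicate 1 (1.78), and not on the rtTA and Sox2xOct4 arrays or Oct4 +DOX replicate 2 (-7.86). Xist, transcribed from the inactive X chromosome, stood at 2.62 to 3.89 on the 5 arrays where Eif2s3y was not well above background, and at -8.18 to -6.01 on the other 5, among them Oct4 +DOX replicate 1 (-6.80). The comparisons within slide 1 and within slide 2 were made between arrays alike in these genes, and all others crossed this difference or, for Oct4 +DOX, had it inside 1 group.

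In TetON-Sox2 mice given DOX, 4 of 25 squamous epithelium genes rose, 4 of 17 stomach and foregut genes rose and 1 fell, and 17 of 30 genes of the enterocyte brush border and digestion fell. Krt6a, a keratin of stratified epithelia, was at least 373-fold higher (10.04 ± 0.93, adjusted p = 0.0018). Adh7 and Aldh3a1, dehydrogenases of alcohols and aldehydes, were at least 156-fold (9.42 ± 0.55, adjusted p = 3.8e-04) and at least 117-fold higher (8.85 ± 0.48, adjusted p = 3.0e-04). Umod, which encodes the kidney protein uromodulin, was at least 360-fold higher (adjusted p = 0.0018), and Lipf, which encodes gastric lipase, rose 165-fold (7.37 ± 0.71, adjusted p = 0.0019). Among the largest falls, Cyp3a25, a cytochrome P450, was at least 229-fold lower (-8.93 ± 1.04, adjusted p = 0.0039), Slc13a1, a sulfate transporter, 458-fold lower (-8.84 ± 1.16, adjusted p = 0.0065) and Ggt1, a gamma-glutamyl transferase, 170-fold lower (-7.41 ± 0.94, adjusted p = 0.0055). Slc5a12, a lactate transporter, was at least 81.4-fold lower. Ugt2b5 and Ugt2b37 were at least 85.5-fold and at least 50.4-fold lower, and Cyp2a5 and Cyp2a4 at least 131-fold and at least 108-fold higher, but probes may cross-hybridise within these near-identical families, so which member changed is uncertain. In all, 1493 of 19052 genes were called, 578 higher and 915 lower, and 869 of them differed by over 4-fold. The groups did not overlap for 66.4% of genes, where chance gives 33.3% and rtTA +DOX against Sox2 -DOX, with 0 genes called, gave 43.2%.

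All 4 arrays of Sox2 +DOX against Sox2 -DOX lay on slide 1. A fit to these 4 arrays alone called 640, of which 543 were among the 1493. The count fell to 165 without Sox2 -DOX replicate 1, 284 without Sox2 -DOX replicate 2 and 234 without Sox2 +DOX replicate 1. Slc13a1 was not called without Sox2 -DOX replicate 1 (-8.72), nor Cyp2a5 (6.97) and Cyp2a4 (6.78) without Sox2 +DOX replicate 1 or in the fit to the 4 arrays. With normexp and quantile normalization, which moved the median of all genes by 0.11, 49.3% of the calls were higher, against 38.7%.

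Of 30 measured genes of the enterocyte brush border and digestion, 17 fell, none rose and 13 did not pass, and 27 fell when adjusted over the list alone. Their median log2 change was -3.21 (camera adjusted p = 1.1e-13, adjusted p = 0.77 with an estimated correlation). Cubn, the intestinal receptor for vitamin B12 bound to intrinsic factor, fell 18.5-fold (-4.21 ± 0.65, adjusted p = 0.01), Slc7a9, part of an amino acid transporter, fell 15-fold (-3.91 ± 0.57, adjusted p = 0.009) and Dpp4, a brush border peptidase, fell 6.06-fold (-2.60 ± 0.38, adjusted p = 0.009). Among 26 genes of lipid absorption and lipoproteins, 8 fell and 1 rose, and 17 fell and 2 rose when adjusted over the list alone (median -1.61, camera adjusted p = 1.2e-05, adjusted p = 0.79 with an estimated correlation). Mttp, which loads lipid onto lipoproteins, fell 10.3-fold (-3.37 ± 0.53, adjusted p = 0.012), and the member that rose was Dhrs9, a retinol dehydrogenase, 21.7-fold higher (4.44 ± 0.34, adjusted p = 7.6e-04). Of 23 intestinal transcription factors, 5 fell and 2 rose, and 8 fell and 2 rose when adjusted over the list alone (median -1.19, camera adjusted p = 0.016, adjusted p = 0.79 with an estimated correlation). Foxa2, a regulator of endoderm, rose 4.17-fold (2.06 ± 0.29, adjusted p = 0.0075), and Creb3l3, a regulator of lipid genes, fell 3.79-fold (-1.92 ± 0.37, adjusted p = 0.022).

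Several of these calls were lost when 1 array was left out. Without Sox2 -DOX replicate 1, Cubn (-4.03), Slc7a9 (-3.68), Dpp4 (-2.52), Mttp (-2.91), Foxa2 (2.06) and Creb3l3 (-1.75) were no longer called, nor was the list of intestinal transcription factors (-1.0). Without Sox2 -DOX replicate 2 this held for Cubn (-4.39), Dpp4 (-2.68), Foxa2 (2.06) and Creb3l3 (-2.10), and without Sox2 +DOX replicate 1 for Cubn (-3.39), Mttp (-2.73), Foxa2 (1.86), Creb3l3 (-1.90) and the list of intestinal transcription factors (-0.31). Slc7a9, Dpp4 and Mttp were also not called in the fit to the 4 arrays alone, at -3.91, -2.60 and -3.37.

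Of 17 measured stomach and foregut genes, 4 rose and 1 fell, also when adjusted over the list alone (median 0.73, or 0.40 with genes near background at their bounds, camera adjusted p = 0.021, adjusted p = 0.77 with an estimated correlation). Besides Lipf, Anxa10, an annexin of gastric epithelium, was at least 33-fold higher (6.73 ± 0.94, adjusted p = 0.0076), and Aqp5, a water channel, was at least 5.2-fold lower (-2.38 ± 0.44, adjusted p = 0.019). Of 25 squamous epithelium genes, 4 rose and none fell, and 5 rose when adjusted over the list alone (median 0.72, or 0.58 with bounds, camera adjusted p = 0.0094, adjusted p = 0.77 with an estimated correlation). These were Krt6a, the keratin Krt4 (at least 33.2-fold, 7.12 ± 1.19, adjusted p = 0.013), Ivl, which encodes involucrin (at least 15.5-fold, 6.00 ± 1.17, adjusted p = 0.023), and the fatty acid binding protein Fabp5 (at least 3.02-fold, 2.81 ± 0.49, adjusted p = 0.015). The stomach and foregut list was not called without Sox2 -DOX replicate 1 (0.41), with a floor at the lowest signal well above background (0.40) or after normexp and quantile normalization (0.24), which also ended the call of Fabp5 (0.47). Without Sox2 -DOX replicate 1, Krt4 (7.04), Ivl (5.92) and Aqp5 (-2.70) were not called. Without Sox2 -DOX replicate 2, Krt4 (7.19), Ivl (6.08), Anxa10 (6.25), Aqp5 (-2.06) and Fabp5 (2.12) were not, and without Sox2 +DOX replicate 1, Ivl (5.77), Anxa10 (6.44), Aqp5 (-2.02) and Fabp5 (2.84) were not. In the fit to the 4 arrays of slide 1, Aqp5 (-2.38) and Fabp5 (2.81) were not called.

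Interferon response and T cell genes were lower with DOX in TetON-Sox2 mice. Of 30 interferon response genes, 18 fell and none rose, and 26 fell when adjusted over the list alone (median -2.21, camera adjusted p = 1.1e-13, adjusted p = 0.77 with an estimated correlation). Cxcl9, a chemokine that attracts T cells, fell 17.6-fold (-4.13 ± 0.41, adjusted p = 0.0021), Cxcl10, its relative, fell 10.3-fold (-3.37 ± 0.46, adjusted p = 0.0074) and Oas3, an antiviral enzyme, fell 13.7-fold (-3.78 ± 0.59, adjusted p = 0.011). Of 24 T cell genes, 9 fell and none rose, and 18 fell when adjusted over the list alone (median -1.73, camera adjusted p = 5.3e-08, adjusted p = 0.77 with an estimated correlation). Among them Cd3d, part of the T cell receptor complex, fell 4.22-fold (-2.08 ± 0.35, adjusted p = 0.014). Of 23 antimicrobial and acute mucosal response genes, 9 fell and 3 rose, and 9 fell and 4 rose when adjusted over the list alone, while the list itself was not called (camera adjusted p = 0.21). Reg3a, a secreted antimicrobial lectin, fell 59.9-fold (-5.91 ± 0.41, adjusted p = 5.7e-04) and Reg1, a relative, rose 47.5-fold (5.57 ± 0.55, adjusted p = 0.002). Of 23 macrophage and granulocyte genes, 1 rose and none fell, and the list was not called (median -0.24, camera adjusted p = 0.31). Of 20 B cell and plasma cell genes, 0 were called by limma, also when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. All 20 had values below 0, and the list was called (median -0.91, camera adjusted p = 0.0048, adjusted p = 0.79 with an estimated correlation). It was not called without Sox2 -DOX replicate 1 (-0.66) or Sox2 +DOX replicate 2 (-0.58). Without Sox2 +DOX replicate 1, Cxcl10 (-3.35), Oas3 (-3.23) and Cd3d (-1.89) were not called. The same held for Oas3 (-3.30) and Cd3d (-1.67) without Sox2 -DOX replicate 1, for Cxcl10 (-2.94) without Sox2 -DOX replicate 2, and for Cd3d (-2.08) in the fit to the 4 arrays alone.

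Adipocyte and smooth muscle lists were also called. Of 15 adipocyte genes, 4 fell and none rose, and 6 fell when adjusted over the list alone (median -2.88, or -2.67 with bounds, camera adjusted p = 7.9e-04, adjusted p = 0.79 with an estimated correlation). Lipe, hormone-sensitive lipase, fell 6.38-fold (-2.67 ± 0.35, adjusted p = 0.0066), a call lost without Sox2 -DOX replicate 1 (-2.77) or 2 (-2.58). Of 22 smooth muscle genes, 1 fell (median -1.27, camera adjusted p = 0.0078, adjusted p = 0.79 with an estimated correlation), and the list was not called without Sox2 -DOX replicate 1 (-1.05) or Sox2 +DOX replicate 2 (-1.12). Of 24 fibroblast and matrix genes, 1 fell, and of 19 enteric neuron and glia genes 0 were called by limma and 1 was lower at an unadjusted p under 0.05, and neither list was called (medians -0.48 and -0.76, camera adjusted p = 0.26 and 0.12). Of 32 cell cycle genes, 0 were called by limma and 3 were higher at an unadjusted p under 0.05, while the list lay higher (median 1.03, camera adjusted p = 7.0e-05, adjusted p = 0.79 with an estimated correlation). It was not called without Sox2 +DOX replicate 1 (0.44). Of 26 enteroendocrine genes, 2 rose and 3 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.8). Insm1, a regulator of endocrine cells, rose 26.3-fold (4.72 ± 0.65, adjusted p = 0.0071) and Nts, which encodes neurotensin, fell 8.04-fold (-3.01 ± 0.42, adjusted p = 0.0077). Insm1 was not called without Sox2 +DOX replicate 1 (4.65) or Sox2 -DOX replicate 2 (4.13), nor Nts without Sox2 -DOX replicate 1 (-2.73) or in the fit to the 4 arrays alone (-3.01). Of 25 cholesterol synthesis genes, 0 were called by limma, also when adjusted over the list alone, and 8 were lower at an unadjusted p under 0.05. The list lay lower (median -0.54, camera adjusted p = 0.0078, adjusted p = 0.77 with an estimated correlation). Its call was lost without Sox2 -DOX replicate 1 (-0.54). Of 23 goblet cell genes, 1 fell, also when adjusted over the list alone (median -0.76, camera adjusted p = 0.047, adjusted p = 0.79 with an estimated correlation). Of 19 circadian clock genes, 0 were called by limma, also when adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05 (median -0.53, or -0.49 with bounds, camera adjusted p = 0.043, adjusted p = 0.77 with an estimated correlation). Neither of these 2 lists was called without Sox2 -DOX replicate 1 (-0.80 and -0.71), without Sox2 +DOX replicate 1 (-0.20 and -0.25), with no filter on dim probes (-0.76 and -0.53) or with the floor (-0.76 and -0.49). The goblet cell list was also not called without Sox2 -DOX replicate 2 (-0.73), in fits to the 4 arrays or without the Oct4 group (both -0.76) or with the authors' values (-0.71). Of the 35 lists, 14 were called in this comparison, 3 higher and 11 lower. In rtTA +DOX against Sox2 -DOX, with 0 genes called, 12 lists were called. With an estimated correlation 0 of the 35 were called in Sox2 +DOX against Sox2 -DOX (smallest adjusted p = 0.77, smallest unadjusted p = 0.039).

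**Figure D2:**
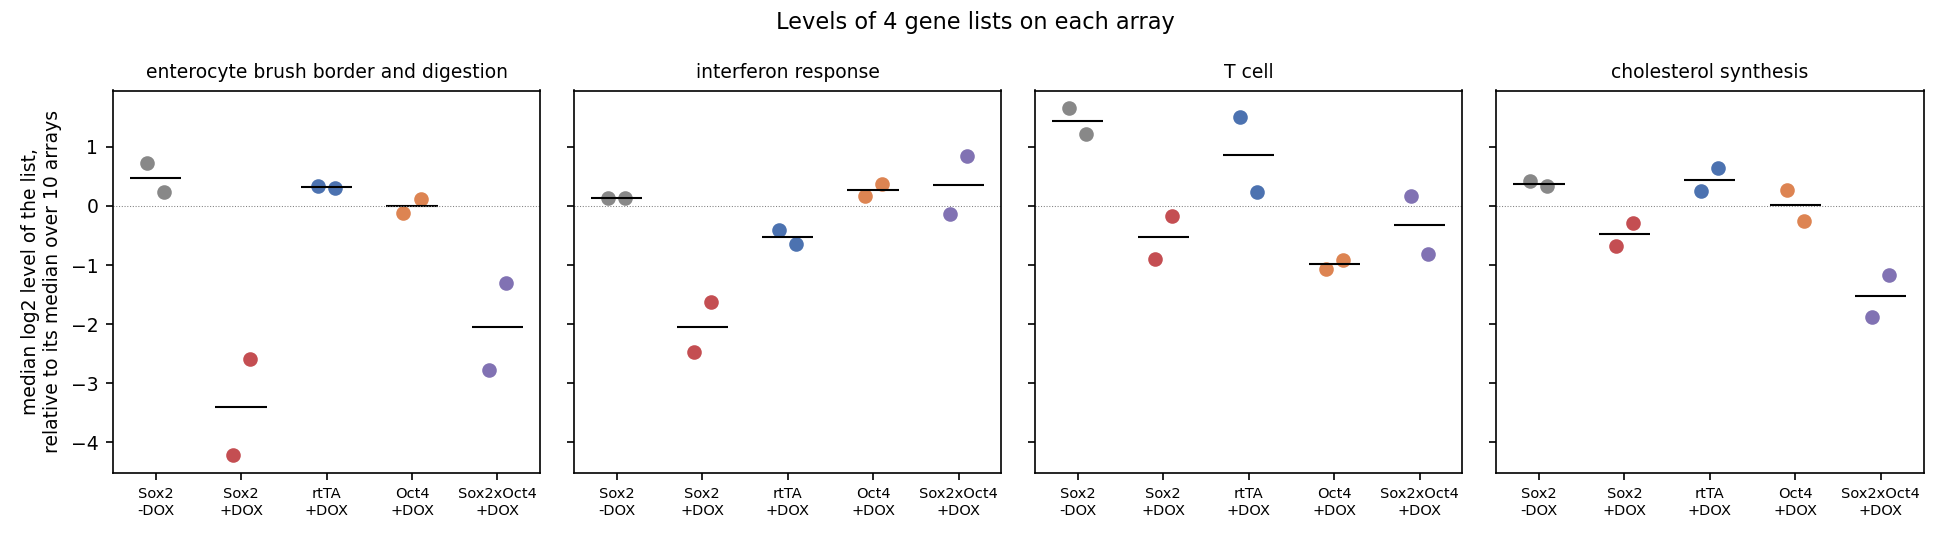
Median log2 level of 4 gene lists (y axis), relative to the list's median over the 10 arrays, on the 2 arrays of each of the 5 groups (x axis). Points are arrays and bars are group means. The brush border list is lowest in Sox2 +DOX, as is the interferon list, and the cholesterol synthesis list is lowest in Sox2xOct4 +DOX.

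Comparison with rtTA +DOX removes DOX as a difference between the groups and adds that of slide and of sex-linked genes. It uses the same 2 Sox2 +DOX arrays as the comparison with Sox2 -DOX, so it is no independent repeat. Here too Sox2 +DOX had higher Umod (at least 619-fold, adjusted p = 8.8e-04), Krt6a (at least 640-fold, adjusted p = 0.0012), Adh7 (at least 269-fold, adjusted p = 2.3e-04) and Aldh3a1 (at least 201-fold, adjusted p = 2.1e-04). Sox21 was 97.5-fold higher (6.61 ± 0.66, SE, n = 2 against 2, adjusted p = 0.0019). Cyp3a25 was at least 414-fold lower (-9.79 ± 1.04, adjusted p = 0.0025). Of 30 brush border genes, 20 fell and 26 fell when adjusted over the list alone (median -3.24, camera adjusted p = 2.2e-13, adjusted p = 0.66 with an estimated correlation). Of 30 interferon response genes, 8 fell and 17 fell when adjusted over the list alone (median -1.29, camera adjusted p = 4.0e-07, adjusted p = 0.66 with an estimated correlation). Among 24 T cell genes 2 fell, also when adjusted over the list alone (median -0.96, camera adjusted p = 1.9e-04, adjusted p = 0.66 with an estimated correlation). In this comparison 17 of the 35 lists were called, 3 higher and 14 lower, where rtTA +DOX against Sox2 -DOX gave 12. With an estimated correlation 0 of the 35 were called (smallest adjusted p = 0.66). The stomach and foregut list had 4 of 17 members higher and the squamous list 5 of 25, with medians of 0.62 and 0.50 (camera adjusted p = 0.0022 and 0.018, both adjusted p = 0.66 with an estimated correlation), and 5 of each when adjusted over the list alone. In all, 1596 genes were called, 616 higher and 980 lower. The count was 935 in a fit to the groups compared, 288 without Sox2 +DOX replicate 1, 195 without rtTA +DOX replicate 1 and 409 without rtTA +DOX replicate 2, and the squamous list was not called without rtTA +DOX replicate 1 (0.31). With normexp and quantile normalization 49.7% of the calls were higher, against 38.6%. Eif2s3y was among the genes that rose (at least 380-fold, adjusted p = 0.034) and Xist among those that fell (at least 645-fold, adjusted p = 0.041), and leaving out any 1 array of the 4 ended both calls (10.32 to 11.06 and -10.58 to -9.17).

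In Oct4 +DOX against rtTA +DOX, genes besides Pou5f1 also rose. Asb9, an adaptor of a ubiquitin ligase, was at least 67.3-fold higher (8.30 ± 0.58, SE, n = 2 against 2, adjusted p = 7.8e-04), Sptssb, a subunit of the first enzyme of sphingolipid synthesis, 167-fold (7.38 ± 0.60, adjusted p = 0.0014), Lmo1, a transcriptional cofactor, 92.8-fold (6.54 ± 0.31, adjusted p = 9.6e-05) and Pou3f1, a transcription factor of the same family as Oct4, 91.2-fold (6.51 ± 0.61, adjusted p = 0.0028). Krt6a was at least 33.6-fold higher (6.46 ± 0.93, adjusted p = 0.021). The largest fall was in Defa21, an alpha-defensin of Paneth cells, at least 10700-fold lower (-15.56 ± 0.61, adjusted p = 6.4e-05) and not well above background on either Oct4 array, although probes may cross-hybridise among alpha-defensins. St6galnac1, a sialyltransferase, was at least 13.2-fold lower (-5.80 ± 0.44, adjusted p = 0.0011). In all, 192 genes were called, 138 higher and 54 lower, and 168 differed by over 4-fold.

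Of 25 squamous epithelium genes, 4 rose in Oct4 +DOX and none fell, and 6 rose when adjusted over the list alone (median 0.51, or 0.42 with bounds, camera adjusted p = 2.1e-04, adjusted p = 0.48 with an estimated correlation). Trp63, a regulator of stratified epithelium, was at least 5.39-fold higher (3.62 ± 0.44, adjusted p = 0.01) and Ly6d 3.85-fold (1.94 ± 0.27, adjusted p = 0.019). Of 24 T cell genes, 1 fell and 12 fell when adjusted over the list alone (median -1.13, camera adjusted p = 4.1e-09, adjusted p = 0.48 with an estimated correlation). The 1 was Prf1, which encodes perforin, at least 3.77-fold lower (-2.94 ± 0.45, adjusted p = 0.028). Of 23 antimicrobial and acute mucosal genes, 1 rose and 6 rose when adjusted over the list alone (median 0.99, or 0.72 with bounds, camera adjusted p = 5.9e-04, adjusted p = 0.48 with an estimated correlation). The 1 was S100a9, a calprotectin subunit of neutrophils, 14.7-fold higher (3.88 ± 0.58, adjusted p = 0.024). Of 30 interferon response genes, 0 were called by limma, 5 were higher at an unadjusted p under 0.05 and 2 rose when adjusted over the list alone (median 0.37, camera adjusted p = 8.1e-04, adjusted p = 0.91 with an estimated correlation). Of 30 brush border genes, 0 were called, also when adjusted over the list alone, and the list was not either (median -0.22, camera adjusted p = 0.3).

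Of the 35 lists, 14 were called in Oct4 +DOX against rtTA +DOX, 6 higher and 8 lower, where rtTA +DOX against Sox2 -DOX gave 12. With an estimated correlation 0 of the 35 were called (smallest adjusted p = 0.21). The smallest belonged to 19 circadian clock genes, of which 1 fell, and 6 fell and 1 rose when adjusted over the list alone (median -0.93, or -0.67 with bounds, camera adjusted p = 1.2e-04, adjusted p = 0.21 with an estimated correlation). The 1 was Nr1d2, a nuclear receptor of the clock, 3.64-fold lower (-1.86 ± 0.32, adjusted p = 0.041), and leaving out any 1 of the 4 arrays ended its call (-2.13 to -1.60), as did no filter on dim probes and a fit to the groups compared (both -1.86). Limma called 0 of 22 smooth muscle genes (1 lower at an unadjusted p under 0.05, median -0.79, camera adjusted p = 0.0069), 0 of 23 goblet cell genes (6 lower, median -0.88, camera adjusted p = 0.0078) and 0 of 26 enteroendocrine genes (3 lower, median -0.55, camera adjusted p = 0.012), all 3 lists with an adjusted p = 0.91 with an estimated correlation. When adjusted over the list alone, 1 goblet cell gene fell and 0 of the other two lists. Higher lists were those of stomach and foregut (2 of 17 genes rose, 3 when adjusted over the list alone, median 0.57, camera adjusted p = 0.012, adjusted p = 0.75 with an estimated correlation) and of tuft cells (1 of 15 rose, also when adjusted over the list alone, median 0.73, or 0.62 with bounds, camera adjusted p = 0.016, adjusted p = 0.91 with an estimated correlation). Without rtTA +DOX replicate 2, 6 lists were called, and those of smooth muscle (-0.27), goblet cells (-0.86), enteroendocrine cells (-0.54) and tuft cells (0.38) were not. Without Oct4 +DOX replicate 1, 9 were called, and smooth muscle (-0.21) and goblet cells (-0.69) were not. The tuft cell median was -0.15 without Oct4 +DOX replicate 2, and the stomach and foregut list was not called without that array (0.55), without rtTA +DOX replicate 1 (0.36) or with normexp and quantile normalization (0.22). No filter on dim probes also ended the calls of the stomach and foregut (0.57) and tuft cell (0.73) lists. The other called lists that lay lower were Paneth cell (1 of 17 members, Defa21, fell, median -0.37, or -0.24 with bounds, and -0.31 for the other 16), intestinal stem cell (0 of 23 called, -0.49) and xenobiotic metabolism (0 of 31, -0.50). The Paneth cell list was not tested without Defa21. Fatty acid oxidation and ketogenesis (0 of 24, 0.39) lay higher. In this order the lists had camera adjusted p = 0.035, 0.018, 0.0069 and 0.022, and adjusted p = 0.91, 0.48, 0.91 and 0.91 with an estimated correlation. None of these was called without rtTA +DOX replicate 2 (0.18, -0.36, -0.55 and 0.27), nor the first 3 without Oct4 +DOX replicate 1 (-0.28, -0.49 and -0.47) and the last without Oct4 +DOX replicate 2 (0.13), with no filter (0.39), with quantile normalization (0.30) or with normexp and quantile normalization (0.27).

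Batch and group cannot be told apart in this comparison. The count of 192 was 35 without rtTA +DOX replicate 1, 49 without rtTA +DOX replicate 2, 97 without Oct4 +DOX replicate 2 and 116 with normexp and quantile normalization. Leaving out rtTA +DOX replicate 1 ended the calls of Krt6a (5.81), Trp63 (3.97), Ly6d (1.70), Prf1 (-2.64) and S100a9 (3.71), and rtTA +DOX replicate 2 those of Krt6a (7.11), Trp63 (3.28), Ly6d (2.19), Prf1 (-3.24), S100a9 (4.05) and the interferon list (0.13). Without Oct4 +DOX replicate 1, Krt6a (6.61), Ly6d (1.99) and Prf1 (-2.78) were not called, and without Oct4 +DOX replicate 2, Krt6a (6.30), Ly6d (1.89), Prf1 (-3.10) and S100a9 (3.21) were not. Normexp and quantile normalization ended the calls of Krt6a (2.01), Trp63 (0.51), Prf1 (-0.53) and S100a9 (2.28), a floor at the lowest signal well above background that of Prf1 (-1.91) and a fit to the groups compared that of Ly6d (1.94).

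With both transgenes, Calca, which encodes the neuropeptide CGRP and calcitonin, was at least 2060-fold higher than in rtTA +DOX (11.01 ± 1.09, SE, n = 2 against 2, adjusted p = 0.0026) and Lipf at least 1480-fold (10.69 ± 0.71, adjusted p = 4.1e-04). Slc7a3, a transporter of cationic amino acids, rose 181-fold (7.50 ± 0.41, adjusted p = 1.7e-04), and Nr0b1, a nuclear receptor expressed in embryonic stem cells, was at least 34.2-fold higher (7.14 ± 0.36, adjusted p = 1.7e-04). Krt6a was at least 51.1-fold higher (7.06 ± 0.93, adjusted p = 0.0076) and Trp63 at least 16.4-fold (5.23 ± 0.44, adjusted p = 0.0012). St6galnac1 and Hao2, an oxidase of hydroxy acids, were at least 18.3-fold (-6.26 ± 0.44, adjusted p = 5.5e-04) and at least 28.3-fold lower (-6.18 ± 0.44, adjusted p = 5.5e-04). In all, 1208 genes were called, 608 higher and 600 lower, and 709 differed by over 4-fold. The groups did not overlap for 52.7% of genes, where chance gives 33.3% and rtTA +DOX against Sox2 -DOX, with 0 genes called, gave 43.2%. Sox2xOct4 +DOX and rtTA +DOX both lay on slide 2. A fit to these 4 arrays alone called 473, of which 410 were among the 1208. The count was 105 without rtTA +DOX replicate 1, 206 without rtTA +DOX replicate 2 and 360 without Sox2xOct4 +DOX replicate 1. Krt6a was not called without rtTA +DOX replicate 1 (6.41) or with normexp and quantile normalization (2.54).

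Cholesterol synthesis genes fell with both transgenes, 11 of 25 and 18 when adjusted over the list alone, and none rose (median -1.61, camera adjusted p = 6.6e-13, adjusted p = 0.22 with an estimated correlation). The list was also called within slide 1 (median -0.54), where limma called 0 members and 8 were lower at an unadjusted p under 0.05. That call was lost without Sox2 -DOX replicate 1 (-0.54), and had an adjusted p = 0.77 with an estimated correlation. Cyp51, lanosterol demethylase, fell 4.8-fold (-2.26 ± 0.32, adjusted p = 0.0098), Sqle, squalene epoxidase, fell 3.65-fold (-1.87 ± 0.28, adjusted p = 0.012) and Mvd, an enzyme of the mevalonate pathway, fell 3.56-fold (-1.83 ± 0.28, adjusted p = 0.012). Of 30 brush border genes, 6 fell and none rose, and 18 fell when adjusted over the list alone (median -2.17, camera adjusted p = 3.8e-11, adjusted p = 0.63 with an estimated correlation). Eps8, an actin regulator of microvilli, fell 3.42-fold (-1.77 ± 0.28, adjusted p = 0.014). Of 26 lipid absorption genes, 8 fell and 1 rose, and 15 fell and 2 rose when adjusted over the list alone (median -1.74, camera adjusted p = 6.2e-05, adjusted p = 0.63 with an estimated correlation). Mttp fell 9.88-fold (-3.30 ± 0.53, adjusted p = 0.014), and Cd36, a fatty acid transporter, was the member that rose, 10-fold (3.32 ± 0.48, adjusted p = 0.01). Without rtTA +DOX replicate 1 none of Cyp51 (-2.04), Sqle (-1.84), Mvd (-1.75), Eps8 (-1.67), Mttp (-2.98) and Cd36 (2.92) was called. Without rtTA +DOX replicate 2, Sqle (-1.89), Mvd (-1.91), Eps8 (-1.88) and Mttp (-3.63) were not, and without Sox2xOct4 +DOX replicate 1, Mttp (-2.88) was not. In the fit to the 4 arrays of slide 2, Sqle (-1.87), Mvd (-1.83) and Eps8 (-1.77) were not called.

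Of 25 squamous epithelium genes, 4 rose with both transgenes and none fell, and 7 rose when adjusted over the list alone (median 0.74, camera adjusted p = 0.0095, adjusted p = 0.63 with an estimated correlation). Of 17 stomach and foregut genes, 3 rose, Lipf, Trp63 and Anxa10 (at least 55.5-fold, 6.95 ± 0.94, adjusted p = 0.0079), none fell and 4 rose when adjusted over the list alone (median 0.46, or 0.36 with bounds, camera adjusted p = 0.019, adjusted p = 0.63 with an estimated correlation). Normexp and quantile normalization ended the calls of both lists, at 0.28 and 0.04. The squamous list was not called without rtTA +DOX replicate 1 (0.69) either, nor the stomach and foregut list without Sox2xOct4 +DOX replicate 2 (0.37). Among the interferon response genes, 5 of 30 rose and none fell, and 8 rose when adjusted over the list alone, while the list was not called (median 0.35, camera adjusted p = 0.072). Ifi44 rose 8.73-fold (3.13 ± 0.36, adjusted p = 0.0045) and Oas2, an antiviral enzyme, 8.31-fold (3.05 ± 0.44, adjusted p = 0.0097). Ifi44 was not called without rtTA +DOX replicate 1 (3.08), nor Oas2 without rtTA +DOX replicate 2 (2.62) or Sox2xOct4 +DOX replicate 1 (2.84). Reg3a fell 32.5-fold (-5.02 ± 0.41, adjusted p = 0.001), S100a9 rose 41.7-fold (5.38 ± 0.58, adjusted p = 0.0036) and Gsta3, a glutathione transferase, rose 19.3-fold (4.27 ± 0.38, adjusted p = 0.0017). Of 22 smooth muscle genes, 1 fell (median -0.70, camera adjusted p = 0.029, adjusted p = 0.93 with an estimated correlation), and of 15 adipocyte genes 1 fell (median -1.39, camera adjusted p = 0.0084, adjusted p = 0.76 with an estimated correlation). Without Sox2xOct4 +DOX replicate 1 the medians of both were above 0, at 0.54 and 0.97. Without rtTA +DOX replicate 2 neither was called, at -0.19 and -1.18.

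Of the 35 lists, 15 were called with both transgenes, 2 higher and 13 lower, where rtTA +DOX against Sox2 -DOX gave 12. With an estimated correlation 0 of the 35 were called (smallest adjusted p = 0.22). Of 24 T cell genes, 0 were called by limma, also when adjusted over the list alone, and 8 were lower at an unadjusted p under 0.05. The list lay lower (median -0.65, or -0.62 with bounds, camera adjusted p = 0.0019, adjusted p = 0.66 with an estimated correlation). It was not called without rtTA +DOX replicate 1 (-0.31) or Sox2xOct4 +DOX replicate 2 (-0.55). Of 31 xenobiotic metabolism genes, 4 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (median -1.04, camera adjusted p = 1.7e-04, adjusted p = 0.63 with an estimated correlation). Of 22 genes of the unfolded protein response, 0 were called by limma, 6 were lower at an unadjusted p under 0.05 and 3 when adjusted over the list alone (median -0.70, camera adjusted p = 1.7e-04, adjusted p = 0.63 with an estimated correlation). Of 23 goblet cell genes, 1 fell, also when adjusted over the list alone (median -0.83, camera adjusted p = 3.0e-04, adjusted p = 0.63 with an estimated correlation). Of 19 circadian clock genes, 2 fell and 3 when adjusted over the list alone (median -0.66, or -0.55 with bounds, camera adjusted p = 0.0031, adjusted p = 0.33 with an estimated correlation). The other lower lists were intestinal transcription factors (median -0.93, camera adjusted p = 0.0031), ileal bile acid handling (-0.61, camera adjusted p = 0.032) and immediate early genes of dissection and stress (-0.63, camera adjusted p = 0.022), all 3 with an adjusted p = 0.63 with an estimated correlation. In these lists 1 of 23 rose, 2 of 11 fell and 4 of 24 fell. When adjusted over the list alone, 1 rose and 5 fell, 2 fell, and 3 rose and 7 fell. Without Sox2xOct4 +DOX replicate 2 the first (-0.79) and the last (-0.85) were not called. Without rtTA +DOX replicate 1 the bile acid list (-1.26) and the immediate early list (-0.44) were not. Normexp and quantile normalization ended the call of the bile acid list (-0.62).

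**Figure D3:**
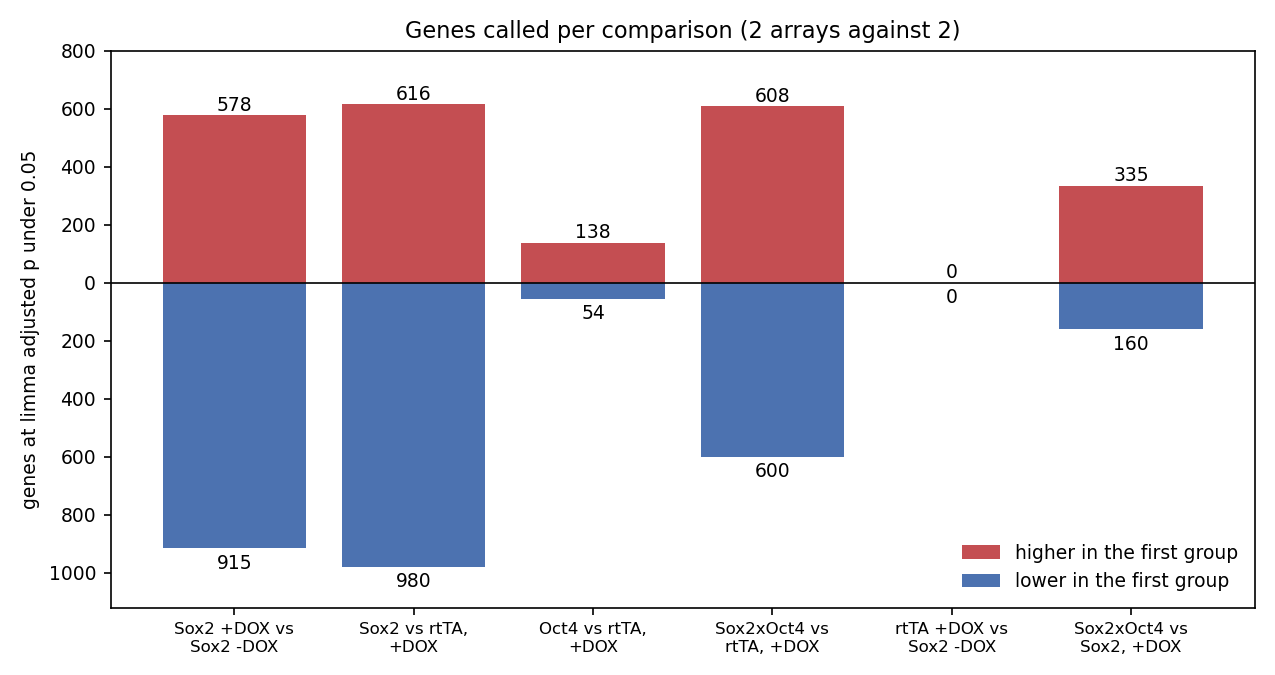
Number of genes called by limma (y axis, genes) in 6 comparisons of 2 arrays against 2 (x axis), with genes higher in the first group drawn upwards from 0 and genes lower drawn downwards. Sox2 +DOX against Sox2 -DOX has 578 higher and 915 lower, and rtTA +DOX against Sox2 -DOX has 0.

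The responses within slide 1 (Sox2 +DOX against Sox2 -DOX) and within slide 2 (Sox2xOct4 +DOX against rtTA +DOX) share no array. Across 19052 genes, which are not independent replicates, their log2 changes had a Pearson r of 0.61 and a covariance of 0.72. Simulated unchanged groups gave 0.00 and 0.00, but every gene and array was drawn independently in them. Without shared arrays these values were fixed in advance, so they are no test of the r. Genes higher in both numbered 215, where independent lists would share 18.4, and genes lower in both 322, where they would share 28.8, and 2 went opposite ways. The r was 0.53 without Sox2 -DOX replicate 1, 0.54 without Sox2 +DOX replicate 1 or without rtTA +DOX replicate 1, and 0.48 without Sox2xOct4 +DOX replicate 1. Against the shared rtTA arrays, Sox2 +DOX and Oct4 +DOX had an r of 0.42 and a covariance of 0.43, where simulated unchanged groups gave 0.50 and 0.12. Genes higher in both numbered 34 (4.46 for independent lists) and lower in both 27 (2.78), where the simulated unchanged groups shared 0 in either direction. Unchanged groups hold no true changes to be called, so this 0 is no test of the overlap. The counts for independent lists take no account of the shared rtTA arrays. Without shared arrays, Sox2 +DOX against Sox2 -DOX and Oct4 +DOX against rtTA +DOX had an r of 0.29 and a covariance of 0.28 (simulated 0.00 and 0.00, again fixed in advance), with 27 genes higher in both (4.19 for independent lists), 15 lower in both (2.59) and 6 opposite. This r was 0.24 without Sox2 +DOX replicate 1 or Oct4 +DOX replicate 1, 0.20 without rtTA +DOX replicate 1 and 0.33 without rtTA +DOX replicate 2.

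The rtTA +DOX and Sox2 -DOX groups, both without an induced transgene, differed in genotype, DOX, the sucrose given with it, slide and sex-linked genes. Here 0 of 19052 genes were called by limma (smallest adjusted p = 0.1), with 1069 at an unadjusted p under 0.05 where chance gives 953. Xist had a log2 difference of 11.28 (adjusted p = 0.45) in a fit whose error takes in the 2 Oct4 arrays, which differ in this gene. With the same error, the smaller -9.87 in Sox2 +DOX against rtTA +DOX was called (limma adjusted p = 0.041). The adjustment depends on the p-values of all genes in a comparison. A fit to these 4 arrays alone called 13, a fit without the Oct4 group 11, the replicate block 2, a variance trend 2 and a floor at the lowest signal well above background 1. Of 30 interferon response genes, 0 were called and 11 were lower at an unadjusted p under 0.05, 2 of them also when adjusted over the list alone (median -0.44, camera adjusted p = 3.7e-06, adjusted p = 0.79 with an estimated correlation). Of 23 antimicrobial and acute mucosal genes, 0 were called and 7 were lower at an unadjusted p under 0.05, all 7 also when adjusted over the list alone (median -0.87, or -0.58 with bounds, camera adjusted p = 2.0e-05, adjusted p = 0.69 with an estimated correlation). Of 24 T cell genes, 0 were called by limma, and 5 were lower and 1 higher at an unadjusted p under 0.05 (median -0.70, camera adjusted p = 5.8e-05, adjusted p = 0.79 with an estimated correlation), and the list was not called without rtTA +DOX replicate 2 (-0.28). Of the 35 lists, 12 were called, 8 higher and 4 lower, and 0 with an estimated correlation (smallest adjusted p = 0.69). Limma called 0 members of the remaining 9 lists, and the counts that follow are at an unadjusted p under 0.05. The B cell and plasma cell list was lower (0 of 20 members, median -0.38, camera adjusted p = 0.037, adjusted p = 0.9 with an estimated correlation). Lists of other tissue layers were higher, with 2 of 19 enteric neuron and glia genes (median 0.80, camera adjusted p = 4.3e-05), 1 of 24 fibroblast and matrix genes (0.50, camera adjusted p = 5.0e-04) and 1 of 22 smooth muscle genes (0.43, camera adjusted p = 0.012). Also higher was the list of immediate early genes of dissection and stress, with 3 of 24 higher and 1 lower (0.44, camera adjusted p = 0.0054). The others were Wnt targets, with 3 of 21 higher and 1 lower (0.51, or 0.30 with bounds, camera adjusted p = 0.0018), and enteroendocrine (5 of 26, 0.41, camera adjusted p = 0.0039), xenobiotic metabolism (4 of 31, 0.25, camera adjusted p = 0.04) and intestinal stem cell genes (3 of 23, 0.23, camera adjusted p = 0.047). The Wnt target and stem cell lists share 9 members. All 8 higher lists had an adjusted p = 0.79 with an estimated correlation but smooth muscle and xenobiotic metabolism, with 0.9. When adjusted over the list alone, 1 enteroendocrine gene was higher and 0 of the other lists. Without Sox2 -DOX replicate 2 the enteroendocrine (0.17), stem cell (0.25), smooth muscle (0.21), xenobiotic (0.16) and immediate early (0.21) lists were not called. The same held without rtTA +DOX replicate 2 for the stem cell (0.04), B cell (-0.33), smooth muscle (0.05) and xenobiotic (0.11) lists, and without Sox2 -DOX replicate 1 for the stem cell (0.16), B cell (-0.38) and fibroblast (0.26) lists. No filter on dim probes ended the call of the B cell list (-0.38), and quantile normalization (0.17) and all probes (0.13) that of the stem cell list.

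Sox2xOct4 +DOX against Sox2 +DOX asks what the Oct4 transgene adds. Pou5f1 was at least 279-fold higher (10.29 ± 0.62, SE, n = 2 against 2, adjusted p = 5.7e-04) and Nr0b1 at least 26.1-fold (6.68 ± 0.36, adjusted p = 3.1e-04), and Aldh3a1 was 45.8-fold lower (-5.52 ± 0.48, adjusted p = 0.0021). The skeletal muscle myosins Myh2 and Myh8 were at least 98.5-fold (8.62 ± 1.26, adjusted p = 0.017) and at least 83-fold higher (7.56 ± 1.22, adjusted p = 0.022). Both were uneven between the 2 Sox2xOct4 arrays, Myh8 at 1.30 and -1.25 against -8.31 to -4.55 on the other 8 arrays, and Myh2, with a spread of 2.80 (SD), at 0.28 on average. Acta1 and Ckm, abundant in skeletal muscle and chosen after their values were seen, gave 0.22 ± 0.99 (adjusted p = 0.93) and 1.39 ± 1.19 (adjusted p = 0.56). The call of Myh8 was lost without Sox2 +DOX replicate 1 (6.77) or 2 (8.34), without Sox2xOct4 +DOX replicate 1 (6.28) and in a fit to the groups compared (7.56), and that of Myh2 without Sox2 +DOX replicate 1 (8.54) or 2 (8.69), with normexp and quantile normalization (3.62) and in a fit to the groups compared (8.62). Interferon response genes were higher for 8 of 30 members and 23 when adjusted over the list alone (median 1.79, camera adjusted p = 6.5e-14, adjusted p = 0.65 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 were lower and 13 when adjusted over the list alone (median -1.08, camera adjusted p = 2.5e-11, adjusted p = 0.3 with an estimated correlation). In all, 495 genes were called, 335 higher and 160 lower, across slides and sex-linked levels that cannot be told apart from the groups. The count was 52 in a fit to the groups compared, 81 without Sox2 +DOX replicate 1, 219 without Sox2 +DOX replicate 2 and 197 without Sox2xOct4 +DOX replicate 2. With normexp and quantile normalization 52.7% of 567 calls were higher, against 67.7%.

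The interaction asks whether both transgenes together gave other log2 changes than the sum of their separate log2 changes, over all 4 groups given DOX. Pou5f1 itself stood at 1.78 in Sox2xOct4 +DOX and 5.49 in Oct4 +DOX. Its interaction was -4.12 ± 0.87 (SE, limma adjusted p = 0.062 over all probes). A departure from the sum cannot be told apart from this difference in Pou5f1 level. Defa21 had an interaction of 15.60 ± 0.86 (SE, n = 2 in each of 4 groups, limma adjusted p = 0.0011). It was not well above background with Oct4 alone, so the size is not measured, and a floor at the lowest signal well above background gave 13.42. Pbld1, a protein with a phenazine biosynthesis-like domain, had 7.64 ± 0.75 (adjusted p = 0.0097), and Krt6a, not well above background in rtTA +DOX, -10.11 ± 1.32 (adjusted p = 0.018, -8.72 with the floor), less than the sum of its separate rises. Of 24 T cell genes, 1 was higher than the sum and 3 when adjusted over the list alone (median 1.66, camera adjusted p = 8.0e-06, adjusted p = 0.71 with an estimated correlation), and of 30 interferon response genes 1 and 8 (median 1.29, camera adjusted p = 3.8e-05, adjusted p = 0.71 with an estimated correlation). Of 25 cholesterol synthesis genes, 0 were called by limma, 8 were lower at an unadjusted p under 0.05 and 2 when adjusted over the list alone (median -0.93, camera adjusted p = 8.0e-06, adjusted p = 0.33 with an estimated correlation). The sex-linked genes Xist and Eif2s3y gave 15.40 and -16.15 (limma adjusted p = 0.068 and 0.062). In all, 270 genes were called, 150 higher and 120 lower. The groups lay on 3 slides and differed in sex-linked genes, so batch, sex-linked levels and group cannot be told apart. Quantile normalization gave 155 higher and 183 lower, and normexp and quantile normalization 80 higher and 93 lower. The count was 105 in a fit to the groups compared, 44 without Sox2 +DOX replicate 1, 175 without Oct4 +DOX replicate 2, 24 without rtTA +DOX replicate 1, 58 without rtTA +DOX replicate 2 and 556 without Sox2xOct4 +DOX replicate 1. Krt6a was not called without Sox2 +DOX replicate 1 (-9.62) or rtTA +DOX replicate 1 (-9.46), or with normexp and quantile normalization (-5.26).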

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

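All tests of explanations in this part, and the comparison of the within-slide responses, were chosen only after the results had been seen. The differences below drew attention because the effect of a transgene or of induction differed between groups, each tested with limma as a difference of differences (2 arrays per group).

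The interaction of the Sox2 and Oct4 transgenes was called for 270 genes and for 16 lists, and for 0 lists with an estimated correlation (smallest adjusted p = 0.33). It cannot be told apart from the differences in slide, sex-linked genes and Pou5f1 level given above. The lists were 9 without Sox2xOct4 +DOX replicate 2 and 25 without Sox2 +DOX replicate 2, and the gene counts without single arrays stand in the report. The genes with the largest values were Defa21 (15.60, adjusted p = 0.0011), Myh2 (9.66, adjusted p = 0.045) and Pbld1 (7.64, adjusted p = 0.0097) above the sum of the separate effects, and Krt6a (-10.11, adjusted p = 0.018), Teddm3 (-8.73, adjusted p = 0.039) and Asb9 (-7.90, adjusted p = 0.0097) below it. Each but Pbld1 was not well above background on either array of at least 1 group, so the sizes are not measured, and with a floor at the lowest signal well above background Defa21 gave 13.42, Krt6a -8.72 and Asb9 -6.17, and Myh2 (6.62) and Teddm3 (-7.19) were not called. Asb9 was not called without rtTA +DOX replicate 1 (-7.57), and Krt6a not without that array (-9.46) or without Sox2 +DOX replicate 1 (-9.62). Myh2 was not called in leave-one-out fits without either Sox2 +DOX array (9.58 and 9.73), either rtTA +DOX array (9.86 and 9.45) or Oct4 +DOX replicate 1 (8.11), nor Teddm3 without these (-8.69, -8.77, -8.94, -8.52 and -7.16) or Sox2xOct4 +DOX replicate 2 (-7.34).

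The response of Sox2xOct4 +DOX against rtTA +DOX (slide 2) differed from that of Sox2 +DOX against Sox2 -DOX (slide 1) for 32 genes, 28 of them higher, and for 4 lists. The slide 1 response also holds DOX and the sucrose given with it, which both slide 2 groups had. The slides also differed in sex-linked genes, so the Oct4 transgene cannot be told apart from these as the source of a difference. With quantile normalization 65.1% of the calls were higher, against 87.5%. The genes were higher for Pou5f1 (11.18, adjusted p = 0.0045), Nr0b1 (7.44, adjusted p = 0.0025) and the olfactory receptor Olfr713 (7.17, adjusted p = 0.0025), which stayed called whichever array was left out, though Pou5f1 (4.99) and Olfr713 (1.92) did not with normexp and quantile normalization. These 3 were well above background only in Sox2xOct4 +DOX among the 4 groups, so the sizes are not measured, and the floor gave 8.91, 5.48 and 5.27. Shisal2b (6.09), Ctnna2 (6.01), Slc7a3 (5.95), Trp63 (5.64) and Oas2 (5.45) were also higher, and Olfr1472 (-4.47) and Ptprt (-4.11) lower, and each lost its call in leave-one-out fits. With the floor Trp63 gave 4.43 and Olfr1472 (-2.42) was not called. Shisal2b lost it without any 1 of the 8 arrays (5.72 to 6.46), Ctnna2 without any but Sox2 +DOX replicate 1 (5.34 to 6.42), Trp63 without any but Sox2xOct4 +DOX replicate 1 (5.30 to 5.99), Olfr1472 and Ptprt without any but Sox2xOct4 +DOX replicate 2 (-4.84 to -3.95 and -4.34 to -3.84), and Slc7a3 and Oas2 without any but the Sox2xOct4 arrays (5.75 to 6.14 and 5.01 to 5.89). The count was 6 without Sox2 -DOX replicate 1, 7 without replicate 2, 10 and 5 without Sox2 +DOX replicates 1 and 2, 6 and 9 without rtTA +DOX replicates 1 and 2, and 52 without Sox2xOct4 +DOX replicate 1, where 11 lists were called, against 2 without rtTA +DOX replicate 2. Of 30 interferon response genes, 2 were higher and 23 when adjusted over the list alone (median 2.46, camera adjusted p = 2.1e-24, adjusted p = 0.28 with an estimated correlation). Of 25 cholesterol synthesis genes, 0 were called by limma and 10 were lower at an unadjusted p under 0.05 (median -0.87, camera adjusted p = 2.1e-08, adjusted p = 0.28 with an estimated correlation). The T cell list (0.94, camera adjusted p = 0.0015) and the brush border list (0.88, camera adjusted p = 0.041) were higher, both with an adjusted p = 0.98 with an estimated correlation. The T cell list was not called without Sox2 +DOX replicate 1 (0.57), rtTA +DOX replicate 2 (0.47) or Sox2xOct4 +DOX replicate 1 (0.75). The brush border list was not called without Sox2 -DOX replicate 1 (0.73), Sox2 +DOX replicate 1 (0.17), rtTA +DOX replicate 1 (1.07), rtTA +DOX replicate 2 (0.93) or Sox2xOct4 +DOX replicate 2 (0.60), or in a fit to the groups compared (0.88).

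Of 30 interferon response genes, 18 fell with DOX in TetON-Sox2 mice (median -2.21, adjusted p = 0.77 with an estimated correlation), and with both transgenes 5 rose and none fell. The scaling of the arrays does not account for this, since the median was still -1.69 after normexp and quantile normalization. DOX itself remains open: the median was -0.44 in rtTA +DOX against Sox2 -DOX and -1.29 in Sox2 +DOX against rtTA +DOX, where both groups had DOX, but both comparisons crossed slides and sex-linked levels. Fewer T cells could also lower the list: 9 of 24 T cell genes fell (median of all 24 -1.73, adjusted p = 0.77 with an estimated correlation). The difference of the medians, -0.47 (permutation p = 0.18, with genes taken as independent), does not separate the lists. The T cell list also lay lower in Oct4 +DOX and Sox2xOct4 +DOX against rtTA +DOX (medians -1.13 and -0.65). The interferon medians there were 0.37 and 0.35. Both lists lay lower in rtTA +DOX against Sox2 -DOX (-0.70 and -0.44) and in Sox2 +DOX against rtTA +DOX (-0.96 and -1.29). The T cell explanation therefore remains open. The biological explanation, an effect of the Sox2 transgene alone, was tested apart from DOX only in Sox2 +DOX against rtTA +DOX. There slide and group cannot be told apart. Within slide 2, where both groups had DOX, the list did not lie lower in Sox2xOct4 +DOX than in rtTA +DOX (median 0.35). The Oct4 transgene was also present in Sox2xOct4 +DOX, so an effect of Sox2 alone remains open.

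Of 17 stomach and foregut and 25 squamous genes, 4 and 4 rose within slide 1 (Sox2 +DOX, adjusted p = 0.77 with an estimated correlation for both lists) and 3 and 4 within slide 2 (Sox2xOct4 +DOX, adjusted p = 0.63 with an estimated correlation), and 1 stomach and foregut gene fell in Sox2 +DOX. Normexp and quantile normalization ended every list call (0.24 for stomach on slide 1, 0.04 and 0.28 on slide 2) but that of the squamous list on slide 1, the floor that of stomach on slide 1 (0.40), and single arrays those of stomach on slide 1 (0.41 without Sox2 -DOX replicate 1), stomach on slide 2 (0.37 without Sox2xOct4 +DOX replicate 2) and squamous on slide 2 (0.69 without rtTA +DOX replicate 1). Stray stomach tissue would bring abundant gland transcripts, but the median change of Gkn3, Tff1, Tff2, Muc5ac, Muc6 and Atp4a was -0.02 (median absolute deviation 0.82, range -0.67 to 2.40) and 0.08 (0.39, range -0.32 to 1.53) in the within-slide comparisons, where Lipf rose by 7.37 and 10.69. Stray squamous tissue would bring the basal keratins Krt5 and Krt14, whose median was 0.67 and 0.51, where Krt6a rose by 10.04 and 7.06 (the second not called without rtTA +DOX replicate 1, 6.41, or with normexp and quantile normalization, 2.54). The gland transcripts argue against stray glandular stomach tissue, and the keratins Krt5 and Krt14 against stray squamous tissue on slide 1. On slide 2 squamous tissue remains open, since Trp63, a regulator of stratified epithelium on the squamous list, also rose there. Other kinds of tissue were not examined. DOX, which both slide 2 groups had, does not account for the rises on slide 2. On slide 1 the Sox2 transgene was not tested apart from DOX.

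Defa21 was at background on both Oct4 arrays. A loss of Paneth cells does not account for it, since the other 16 Paneth cell genes had a median of -0.31 (median absolute deviation 0.82). An inherited difference between mice at the defensin genes might, since Defcr-rs10, chosen after its values were seen, differed by 15.57 between the 2 Sox2 +DOX arrays of 1 group, or by at least 13.59, as it was not well above background on replicate 1. It remains open for Defa21, because both Oct4 arrays were alike and of 1 group. An effect of Oct4 also remains open: Defa21 stood at 6.43 and 8.35 on the Sox2xOct4 arrays, where Pou5f1 was induced as well, but there Pou5f1 stood at 1.78, against 5.49 in Oct4 +DOX, and the Sox2 transgene was present.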

How the results depend on the processing

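The floor, the fit without the Oct4 group and all alternatives for the difference of within-slide responses were chosen only after results had been seen. Of 166 named gene values that were called, quantile normalization kept 166, all probes 165, the variance trend 163, the floor 161, no filter 155, normexp and quantile normalization 140, a fit to only the groups compared 118, the fit without the Oct4 group 134 of 137, the authors' values 39 of 60 and leave-one-out fits 423 of 728. Of 102 list calls, these kept 98, 99, 101, 99, 92, 93, 96, 67 of 72, 13 of 14 and 377 of 488, and an estimated correlation 0 in every comparison. A slide block can change nothing for comparisons within slides and their difference, since each group lay on 1 slide. Comparisons between slides cannot be estimated with it. The cause of each change was not tested, except that fits with fewer arrays have fewer degrees of freedom. Signal over background limits the rest of the probes, beyond the 63.5 to 70.5% that were well above it, to bounds on their fold. Where neither group compared was well above background, no bound can be given.

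Genes called, with no filter, were 933 (Sox2 +DOX against Sox2 -DOX), 1045 (Sox2 +DOX against rtTA +DOX), 776 (Sox2xOct4 +DOX against rtTA +DOX) and 148 (interaction). With no filter the median of all genes moved by -0.20, 0.18, 0.15 and -0.25 in these, by 0.17 in Oct4 +DOX against rtTA +DOX, -0.16 in rtTA +DOX against Sox2 -DOX, -0.11 in Sox2xOct4 +DOX against Sox2 +DOX and 0.22 in the response difference. A fit to only the groups compared called 640, 935, 473 and 105 in the first 4, 13 in rtTA +DOX against Sox2 -DOX and 52 in Sox2xOct4 +DOX against Sox2 +DOX. The authors' values, also fitted to the 4 TetON-Sox2 arrays alone, gave 693 in the first. Normexp and quantile normalization called 116 in Oct4 +DOX against rtTA +DOX, 173 in the interaction and 7 in the response difference, where the variance trend called 16. In rtTA +DOX against Sox2 -DOX the variance trend called 2, the floor 1 and the fit without the Oct4 group 11. Lists called with no filter were 26 in Sox2 +DOX against rtTA +DOX (17 in the main fit) and 8 in the response difference (4 in the main fit), where all probes gave 10. The correlation of the within-slide responses was 0.67 with normexp and quantile normalization and 0.54 with no filter, and that of Sox2 +DOX against Sox2 -DOX with Oct4 +DOX against rtTA +DOX, added after results were seen, 0.34 and 0.21.

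Leave-one-out fits called 165 to 1729 genes (Sox2 +DOX against Sox2 -DOX), 195 to 1675 (Sox2 +DOX against rtTA +DOX), 35 to 191 (Oct4 +DOX against rtTA +DOX), 105 to 1076 (Sox2xOct4 +DOX against rtTA +DOX), 81 to 679 (Sox2xOct4 +DOX against Sox2 +DOX), 24 to 556 (interaction) and 5 to 52 (response difference). Lists called ran from 6 to 19 in Oct4 +DOX against rtTA +DOX, 8 to 17 in Sox2xOct4 +DOX against Sox2 +DOX, 9 to 25 in the interaction and 2 to 11 in the response difference. The correlations ran from 0.48 to 0.64 (within slides), 0.30 to 0.51 (Sox2 and Oct4), 0.51 to 0.70 (Sox2 and both), 0.38 to 0.55 (Oct4 and both) and 0.20 to 0.33 (the added pair). Sox2 and Oct4, Sox2 and both, and Oct4 and both share the rtTA arrays. Their r with all arrays was 0.42, 0.65 and 0.47, where simulated unchanged groups gave 0.50 for each.

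Directions turned in leave-one-out fits for Cdx2, never called, which ran from -1.39 to 0.06 in Sox2 +DOX against rtTA +DOX, -0.51 to 0.35 in Oct4 +DOX against rtTA +DOX (0.06 without rtTA +DOX replicate 2), -1.22 to 0.24 in Sox2xOct4 +DOX against Sox2 +DOX, -1.14 to 0.32 in the interaction (0.02 without Oct4 +DOX replicate 2) and -0.91 to 0.55 in the response difference (0.02 without Sox2 -DOX replicate 2). The tuft cell list ran from -0.15 to 1.84 in Oct4 +DOX against rtTA +DOX and the median of the Paneth cell list from -0.92 to 0.18 (0.18 without rtTA +DOX replicate 2, where it was not called). In Sox2xOct4 +DOX against rtTA +DOX the smooth muscle list ran from -1.92 to 0.54 and the adipocyte list from -2.13 to 0.97. In Sox2xOct4 +DOX against Sox2 +DOX the cell cycle list ran from -1.31 to 0.37 (0.23 without Sox2 +DOX replicate 1) and the smooth muscle list from -0.07 to 2.28. The cell cycle list ran from -1.42 to 0.09 in the interaction.

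The replicate numbers were not taken as pairs, since residual correlations between groups ran from -0.13 to 0.27 and only 5 of 10 were over 0.1, which leaves pairing open. With the replicate number as a block, genes called were 1479 (Sox2 +DOX against Sox2 -DOX), 1674 (Sox2 +DOX against rtTA +DOX), 215 (Oct4 +DOX against rtTA +DOX), 1201 (Sox2xOct4 +DOX against rtTA +DOX), 2 (rtTA +DOX against Sox2 -DOX), 588 (Sox2xOct4 +DOX against Sox2 +DOX), 247 (interaction) and 39 (response difference), and lists called 15, 18, 15, 16, 12, 10, 17 and 4. The block kept 165 of 166 gene calls and 102 of 102 list calls.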

Other observations

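The values below were picked out, and the tests above on defensins chosen, only after the results had been seen. Some alpha-defensin genes split arrays within a group. Defcr-rs10 was at -8.02 and -7.43 on the Sox2 -DOX arrays and -8.31 on Sox2 +DOX replicate 1, and at 7.26 on Sox2 +DOX replicate 2 and 6.79 to 8.30 on the other 6 arrays. A probe of Defcr-rs2 gave -8.20, -5.93, -7.23 and 7.53 on the same 4 arrays and 6.96 to 8.44 on the others. Defa31 gave 4.10, 4.51, 4.03 and 6.97 and, on the others, 6.62 to 8.43. Defa21 stood at 7.99, 7.95, 7.66 and 7.04 there, at -8.34 and -7.97 on the Oct4 arrays, and at 6.92, 7.89, 6.43 and 8.35 on the rtTA and Sox2xOct4 arrays. These genes were chosen after their values were seen, and probes may cross-hybridise among alpha-defensins.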
